A study of Homo sapiens with 6 samples.

How the data were processed

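The series holds 6 RNA-seq libraries of 293T cells, an established human embryonic kidney line that takes up plasmids readily. The cells were transfected with a lipid reagent, with a plasmid labelled GFP in 3 libraries and with a plasmid labelled GFP-812 in the other 3. GFP is a green fluorescent protein used as a tag. The labels do not say what the number in GFP-812 stands for. The series title names truncated NEK1. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

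Per the labels' protocols, messenger RNA was taken from total RNA by its poly(A) tail on oligo(dT) beads, fragmented, copied from random primers and amplified by PCR. The ribosomal RNA made by RNA polymerase I and its precursor carry no such tail and were not analysed here. Among mitochondrially encoded transcripts, those of the ribosomal RNA genes MT-RNR1 and MT-RNR2 were tested. Per the submitters' processing notes, the tools were FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.2.1 and HTSeq 0.6.1, with the genome build hg38. Whether the counting used strand, and which annotation release it used, are not given in the sources used here. Counts of genes that overlap, or of genes with near-identical copies such as the ribosomal protein genes and their pseudogenes, could therefore be split or shared.

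The authors deposited 1 table of 61806 Ensembl genes with raw counts for each library. Per the file headers, the same table gives FPKM, a count scaled by gene length and library total, for each library. Dividing each count by the exonic size in the table and by the library's own total returned the FPKM for 100% of values within 0.0051, so the FPKM carry no further normalization. No row lacked a gene. Gene positions are those of the table, on hg38. Total counts were 14255148, 15617457 and 17613814 in GFP-812 replicates 1, 2 and 3, and 16144531, 16089894 and 16061389 in GFP replicates 1, 2 and 3.

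The tests were fixed before the data were examined. The design asked for limma on log2(FPKM + 1) unless raw counts were present, and for edgeR's quasi-likelihood test on the counts if they were. Since the table holds counts, edgeR 4.0.16 in R 4.3.3 was used (filterByExpr, TMM scaling, group as the single term), with 2-sided p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. It tested 16834 genes. The design also named a minimum mean FPKM of 1, which was written for limma; edgeR used its own filter, and the FPKM minimum was run as an added alternative. Standard errors of log2 fold changes were computed from the F statistic. Fold changes from edgeR are on the log2 scale of scaled counts. Levels are given as FPKM, mean ± SD over 3 libraries. NEK1 was also compared by an exact permutation test on log2(FPKM + 1), which cannot go below p = 0.1 with 3 against 3.

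A set of 36 gene lists with 1056 entries was fixed before the data were examined, and each entry matched a row of the table. The lists cover ribosome production, stress responses, DNA repair, the cilium, the cell cycle, metabolism, RNA quality and markers of other cell types. The 33 lists with at least 5 members at a mean FPKM of at least 1 were tested with camera in limma 3.58.1 on log2(FPKM + 1), over 12984 genes, with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Members are called risen or fallen by edgeR at an adjusted p under 0.05 over all genes tested, and the number adjusted over the list alone is given as well. A list score is the mean log2 CPM of its members in a library minus that library's median over all genes tested.

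The genes named were chosen by a rule fixed before the data were examined. It took NEK1 and the 8 risen and 8 fallen genes with the largest log2 fold change among genes with a symbol, an adjusted p under 0.05, a mean FPKM of at least 5 in the higher group and no overlap between the groups. From each list that passed camera or had 3 or more members past the threshold it also took the 2 members with the smallest p, or 4 for the lists on ribosome production. NDRG1 is named under 2 parts of the rule. The values of 1 gene that the rule took are not reported here.

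Alternatives were limma on log2(FPKM + 1) with other pseudocounts, scalings, variance settings and library weights, DESeq2 1.42.0, edgeR with other filters and scalings, protein-coding genes alone, the replicate number as a block, and leaving out each library in turn. Added after the data were examined were limma-voom, limma on log2 CPM, robust edgeR, limma at a mean FPKM of at least 20, total-count scaling, camera with trended variance, camera on log2 CPM, member counts of the lists without each library, and a correction for GC content and exonic size. The correction removed from each library a spline with 4 degrees of freedom on each property. GC content was that of the longest GENCODE release 29 transcript, matched by Ensembl ID for 98.2% of the genes tested.

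The edgeR step was tested on simulated counts for this comparison with 200 changed genes, and 16524 genes in all passed its filter. It recovered 58.8% of the genes changed by 0.3 on the log2 scale, 90.9% of those changed by 0.58 and 100% of those changed by 1, and 4.05% of its calls were false. Changes were put only in genes above a minimum mean count, and each gene was drawn independently. These rates therefore do not carry over to genes with lower counts or to genes that vary together. Replicates were compared by chi-square over genes. The chi-square per degree of freedom was 2.13 to 4.03 within groups and 10.8 to 13.7 between groups, and without NEK1 it was 2.12 to 4.03 within groups and 2.65 to 5.88 between groups, so no 2 libraries agreed within sampling noise. Pearson correlations of log2(FPKM + 1) were 0.9862 to 0.9892 within groups and 0.9844 to 0.9872 between groups. Confidence intervals of shares of counts are exact Clopper-Pearson intervals at 95% and cover counting error only, since PCR copies are not independent molecules.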

Results

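RNA from 293T cells transfected with a GFP plasmid or a GFP-812 plasmid was sequenced in 3 libraries per group, with 14255148 to 17613814 counts per library. The series title concerns nuclear condensates of truncated NEK1 and ribosomal RNA biogenesis, and the comparison asks how the transcriptome of cells given the GFP-812 plasmid differed from that of cells given GFP. NEK1 encodes a protein kinase with known roles in DNA repair and the primary cilium.

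NEK1 (ENSG00000137601, hg38 chromosome 4, 169369704 to 169612632, minus strand) was far higher in GFP-812 cells. Its level was 524.9 ± 35 FPKM (SD, n = 3) in GFP-812 libraries and 3.91 ± 0.085 FPKM (SD, n = 3) in GFP libraries, which edgeR fitted as 135.5-fold (log2 fold change 7.08, SE 0.0468, adjusted p = 4.5e-70). NEK1 took 0.919% of all counts in GFP-812 replicate 1 (95% Clopper-Pearson interval 0.914% to 0.924%), 0.847% in replicate 2 (0.842% to 0.851%) and 0.807% in replicate 3 (0.802% to 0.811%). In the GFP libraries it took 0.00624%, 0.00653% and 0.00639%. The exact 2-sided permutation test over the 6 libraries gave p = 0.1, the smallest value it allows. Counts per gene do not separate NEK1 RNA made from a plasmid from that of the cells' own gene.

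**Figure D1:**
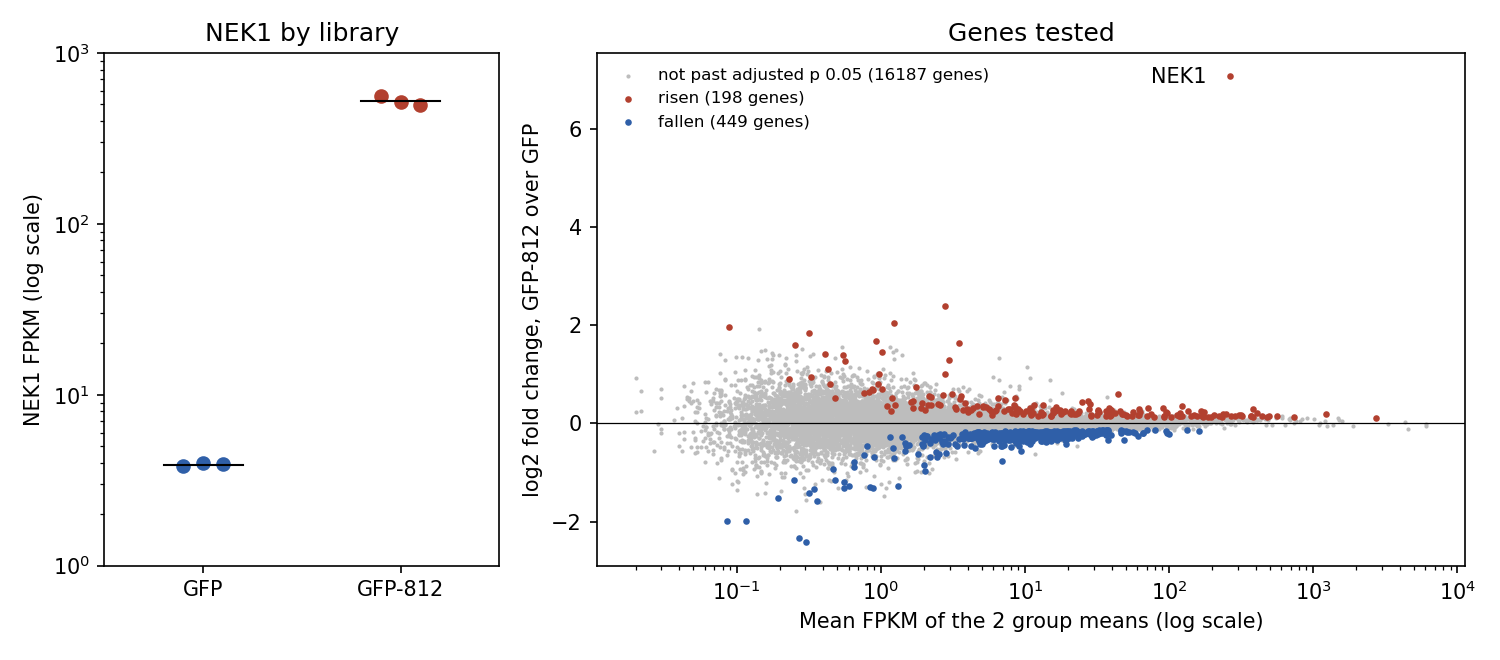
NEK1 level in FPKM in each library on a log axis, with lines at the group means (left), and log2 fold change of GFP-812 over GFP against mean FPKM on a log axis for the 16834 genes tested (right), with 198 risen genes in red, 449 fallen genes in blue and the rest in grey. NEK1 lies at a log2 fold change of 7.08, far from the other genes.

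Outside NEK1, most changes were small. Of 16834 genes tested, 198 rose and 449 fell in GFP-812 cells, so that 69.4% of the 647 changed genes fell. The median absolute log2 fold change was 0.26 among risen genes and 0.23 among fallen genes, and 32 genes changed at least 2-fold, 16 in each direction. With a minimum mean FPKM of 5, NEK1 alone changed at least 2-fold. The largest rises under the naming rule after NEK1 were those of SAT1, which acetylates spermidine and spermine, OSTN, a secreted peptide, NDRG1 and STC1, both known to be induced by hypoxia, ZCCHC12, RPL24P8 and TMEM205. SAT1 (ENSG00000130066, chromosome X, 23783173 to 23786210) stood at 53.2 ± 1.58 FPKM against 35.3 ± 4.82 FPKM (SD, n = 3 each), a 1.52-fold rise (log2 fold change 0.60, SE 0.0567, edgeR adjusted p = 2.7e-11). The log2 fold changes of OSTN, NDRG1, STC1, ZCCHC12, RPL24P8 and TMEM205 were 0.52, 0.51, 0.48, 0.46, 0.44 and 0.38. RPL24P8 is a pseudogene of RPL24 that can share its reads, and its value is uncertain. Falls were led by CREB5, a transcription factor of the CREB family. CREB5 (ENSG00000146592, chromosome 7, 28299321 to 28825894) stood at 7.61 ± 0.296 FPKM against 11.3 ± 0.759 FPKM (SD, n = 3 each), at a log2 fold change of -0.55 (SE 0.0513, edgeR adjusted p = 2.53e-11). ZER1, HELQ, a DNA repair helicase, ZNF654, LTN1, a ubiquitin ligase of ribosome quality control, THAP9, ZMYM5 and CDKN2AIP had log2 fold changes of -0.50, -0.49, -0.46, -0.46, -0.45, -0.45 and -0.44.

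The count of 647 depended on the method and on single libraries: limma on log2(FPKM + 1) called 3 genes and had 2071 genes at an unadjusted p under 0.05 against 2717 in edgeR, DESeq2 called 461, and edgeR called 209 without GFP-812 replicate 2, 292 without GFP-812 replicate 3, 263 without GFP replicate 1, 414 without GFP replicate 2 and 1317 without GFP replicate 3. The count of 32 genes changed at least 2-fold was 3 with limma, 1 with DESeq2, 8 at a mean FPKM of at least 1, 15 without GFP-812 replicate 2, 19 without GFP-812 replicate 3, 13 without GFP replicate 1 and 61 without GFP replicate 3. The calls of STC1 without GFP replicate 1 (log2 fold change 0.29, adjusted p = 0.0733), of TMEM205 without GFP-812 replicate 3 (0.167), GFP replicate 1 (0.167) or GFP replicate 2 (0.114), and of RPL24P8 without each library other than GFP replicates 1 and 3 (0.0694 to 0.258) were lost.

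Among genes whose products build ribosomes, 4 of 51 small-subunit processome members and 3 of 50 large-subunit biogenesis factors were lower in GFP-812 cells. Of the 51 members of the small-subunit processome, the complex that processes pre-ribosomal RNA toward the small subunit, 4 fell, 0 rose and 47 did not pass, with 6 falling when adjusted over the list alone. UTP20 stood at 9.89 ± 0.259 against 12.1 ± 0.559 FPKM (SD, n = 3 each; log2 fold change -0.28, SE 0.0497), and WDR43, RRP12 and PNO1 had log2 fold changes of -0.20, -0.29 and -0.21. The list median was -0.06 and camera passed it downward (adjusted p = 0.000175; adjusted p = 0.463 with an estimated correlation). Of 50 large-subunit biogenesis factors, 3 fell (3 adjusted over the list alone) and 47 did not pass. These were NVL, an ATPase of large-subunit maturation, at 21.5 ± 0.0721 against 25.8 ± 1.63 FPKM (SD, n = 3 each; log2 fold change -0.25, SE 0.0506), NOL8 at -0.23 and TEX10 at -0.19. SDAD1 was next by p, at -0.11 (adjusted p = 0.242). Camera passed this list downward (adjusted p = 0.0247; adjusted p = 0.567 with an estimated correlation), with a median of -0.04.

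The list of RNA polymerase I transcription, the step that makes pre-ribosomal RNA, did not pass camera (adjusted p = 0.251). Of its 19 members 2 fell (3 adjusted over the list alone) and 17 did not pass. The snoRNP proteins (1 of 18 fell; 3 risen and 2 fallen adjusted over the list alone; camera adjusted p = 0.918), the exosome (0 of 16 past the threshold by either adjustment; adjusted p = 0.656) and the snoRNA host genes (2 of 23 fell; 4 risen and 2 fallen adjusted over the list alone; adjusted p = 0.565) did not pass either. Without GFP replicate 3, 4 snoRNA host genes rose and 1 fell, and 2 snoRNP proteins rose and 2 fell. Fallen polymerase I genes numbered 0 without GFP-812 replicates 2 or 3, 1 without GFP-812 replicate 1 or GFP replicate 1 and 3 without GFP replicate 2, and 1 rose without GFP replicate 3. Fallen snoRNA host genes numbered 0 without GFP-812 replicates 2 or 3 and 1 without GFP replicate 1. Fallen snoRNP proteins numbered 0 without GFP-812 replicates 2 or 3 or GFP replicate 1 and 2 without GFP replicate 2. The processome list fell in 1 member without GFP-812 replicate 3 or GFP replicate 1, in 2 without GFP-812 replicate 2 and in 7 without GFP replicate 3, with medians of -0.10 without GFP-812 replicate 1 and -0.04 without GFP replicate 1. The median of the large-subunit biogenesis list was -0.02 without GFP-812 replicate 2 or GFP replicate 1 and -0.06 without GFP replicate 2. It did not pass camera without GFP-812 replicate 3 (adjusted p = 0.0929) or GFP replicate 1 (0.353), nor with median-of-ratios scaling (0.0521), quantile normalization (0.0878) or a minimum mean FPKM of 5 (0.119). The single-gene calls lost were those of WDR43 and PNO1 without GFP-812 replicates 2 or 3 or GFP replicate 1 (adjusted p 0.0593 to 0.171), of RRP12 without GFP-812 replicate 3 (0.105) or GFP replicate 1 (0.068), and of TEX10 without GFP-812 replicates 2 or 3 or GFP replicates 1 or 2 (0.133 to 0.218).

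Of the messenger RNAs of the ribosomal proteins themselves, 16 of 47 and 9 of 32 were higher in GFP-812 cells. Of 47 large-subunit ribosomal protein genes 16 rose, 0 fell and 31 did not pass (40 rose adjusted over the list alone), and of 32 small-subunit genes 9 rose, 0 fell and 23 did not pass (27 rose adjusted over the list alone). All 47 and all 32 fitted log2 fold changes lay above 0, with medians of 0.11 and 0.12. RPL23 stood at 150.5 ± 1.89 against 135.8 ± 7 FPKM (SD, n = 3 each; log2 fold change 0.16, SE 0.0365), and RPL7, RPL11 and RPL35 had log2 fold changes of 0.16, 0.17 and 0.19. RPS25 stood at 392.6 ± 1.4 against 354.5 ± 21.4 FPKM (SD, n = 3 each; log2 fold change 0.16, SE 0.0385), with RPS24 and RPS3 both at 0.14. Camera passed the large-subunit list (adjusted p = 3.02e-11) and the small-subunit list (adjusted p = 6.52e-09) upward; both had an adjusted p = 0.49 with an estimated correlation. The libraries did not split cleanly by group: ribosomal protein genes took 6.36%, 6.42% and 6.42% of counts in the GFP-812 libraries, 5.86% and 5.67% in GFP replicates 1 and 2, and 6.41% in GFP replicate 3. Without GFP replicate 3, 45 large-subunit and 30 small-subunit genes rose. Without GFP-812 replicates 1, 2 or 3 or GFP replicates 1 or 2, 8, 2, 7, 5 and 3 large-subunit genes and 4, 1, 2, 0 and 0 small-subunit genes rose, and both list medians, with the values of RPL11 and RPL35, were lowest without GFP replicate 2 (0.07, 0.07, 0.12 and 0.12). Each of the 7 genes named here lost its call in at least 1 of those 5 fits (adjusted p 0.0572 to 0.171). Values were lowest after quantile normalization of the FPKM for RPL7 (0.02547, limma adjusted p = 0.483), RPL11 (0.04905, 0.55), RPS25 (0.0355, 0.414), RPS3 (0.06885, 0.24) and RPS24 (0.08595, 0.168). RPL35 was lowest after the GC and length correction (0.1193, adjusted p = 0.0605). Ribosomal protein genes have many pseudogene copies, so single values are uncertain.

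**Figure D2:**
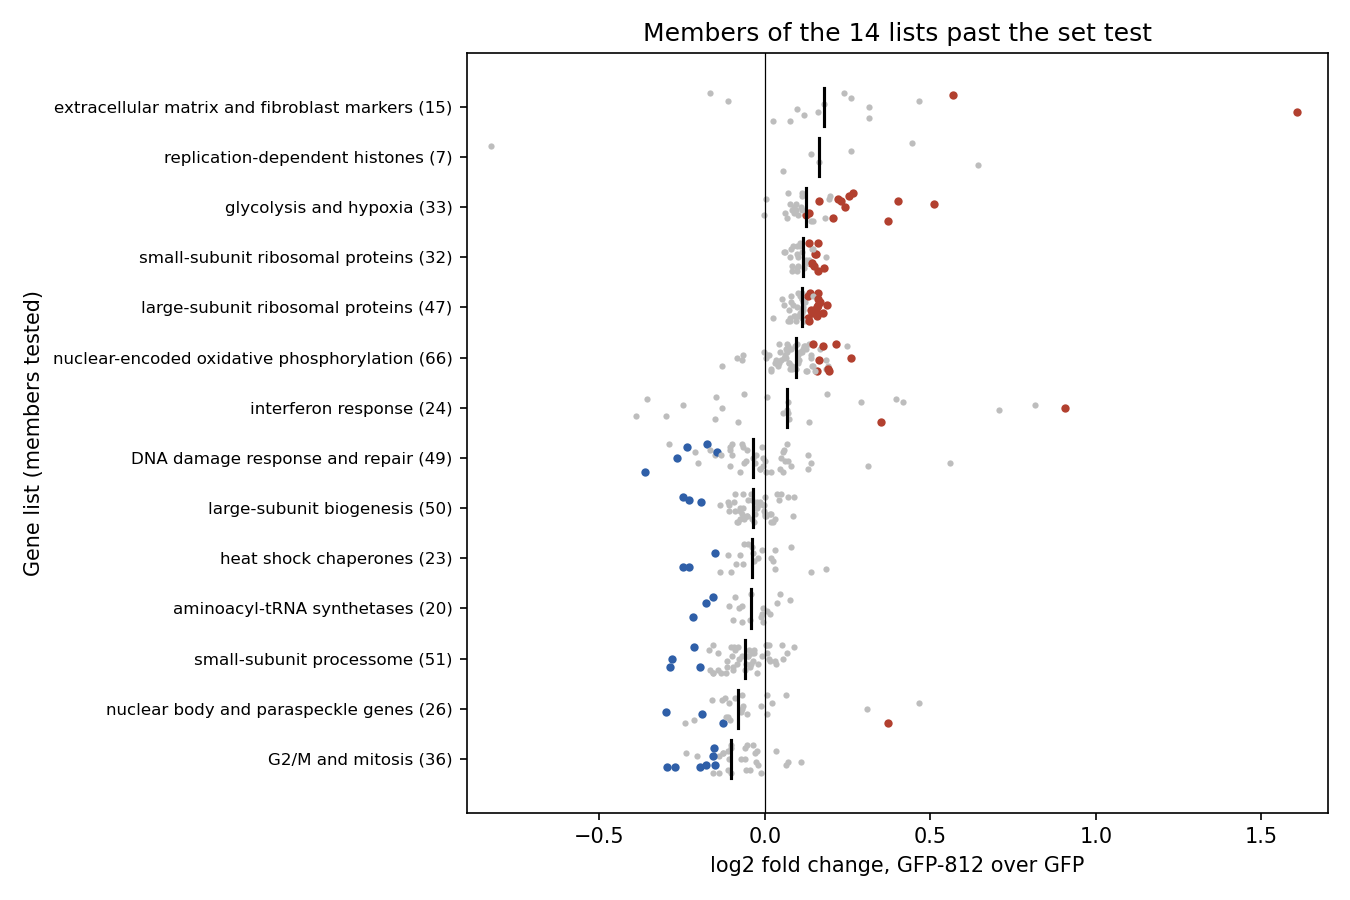
log2 fold change of GFP-812 over GFP for each tested member of the 14 lists that passed camera with its preset correlation, with risen members in red, fallen members in blue, members that did not pass in grey and a black line at the list median. Ribosomal protein genes lie close together around medians of 0.11 and 0.12, while mitosis genes lie around -0.10.

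Of the glycolysis and hypoxia genes 12 of 33, and of the oxidative phosphorylation genes 8 of 66, were higher in GFP-812 cells. On the glycolysis and hypoxia list 12 of 33 members rose, 0 fell and 21 did not pass (18 rose adjusted over the list alone), with a median of 0.12. PGK1, a glycolytic enzyme, stood at 182.5 ± 2.28 against 153.3 ± 9.05 FPKM (SD, n = 3 each; log2 fold change 0.27, SE 0.0366), and NDRG1 at 10.04 ± 1.26 against 7.13 ± 1.15 FPKM (SD, n = 3 each). Of 66 nuclear-encoded oxidative phosphorylation genes 8 rose, 0 fell and 58 did not pass (10 rose adjusted over the list alone), with a median of 0.09. The log2 fold changes of ATP5MC1, a subunit of ATP synthase, and NDUFA1, a subunit of complex I, were 0.26 (SE 0.0665) and 0.19 (SE 0.0505). Camera passed glycolysis and hypoxia (adjusted p = 3.33e-09; adjusted p = 0.463 with an estimated correlation) and oxidative phosphorylation (adjusted p = 1.05e-07; adjusted p = 0.49 with an estimated correlation) upward. Mitochondrially encoded transcripts did not pass (adjusted p = 0.989), with 1 of 15 risen (1 risen and 1 fallen adjusted over the list alone). That gene, named after its value was seen, was the ribosomal RNA gene MT-RNR2 (log2 fold change 0.1206, adjusted p = 0.0272). Risen and fallen mitochondrial transcripts numbered 0 and 0 without GFP-812 replicates 2 or 3 or GFP replicate 1, 1 and 1 without GFP-812 replicate 1, 2 and 1 without GFP replicate 2 and 1 and 2 without GFP replicate 3. Glycolysis scores of GFP replicate 3 and GFP-812 replicate 1 met at 2.79. Risen members numbered 5 without GFP-812 replicate 2 and 6 without GFP replicate 1 on the glycolysis list. On the oxidative phosphorylation list they numbered 4, 0, 2, 2 and 0 without GFP-812 replicates 1, 2 and 3 and GFP replicates 1 and 2, and 14 without GFP replicate 3, with a median of 0.06 without GFP replicate 2. The calls of ATP5MC1 and NDUFA1 were lost in 3 and 4 of the fits without GFP-812 replicates 2 or 3 or GFP replicates 1 or 2 (adjusted p 0.0561 to 0.213). NDUFA1 was at 0.08845 after quantile normalization (limma adjusted p = 0.296) and 0.09637 after the GC and length correction (0.3).

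**Figure D3:**
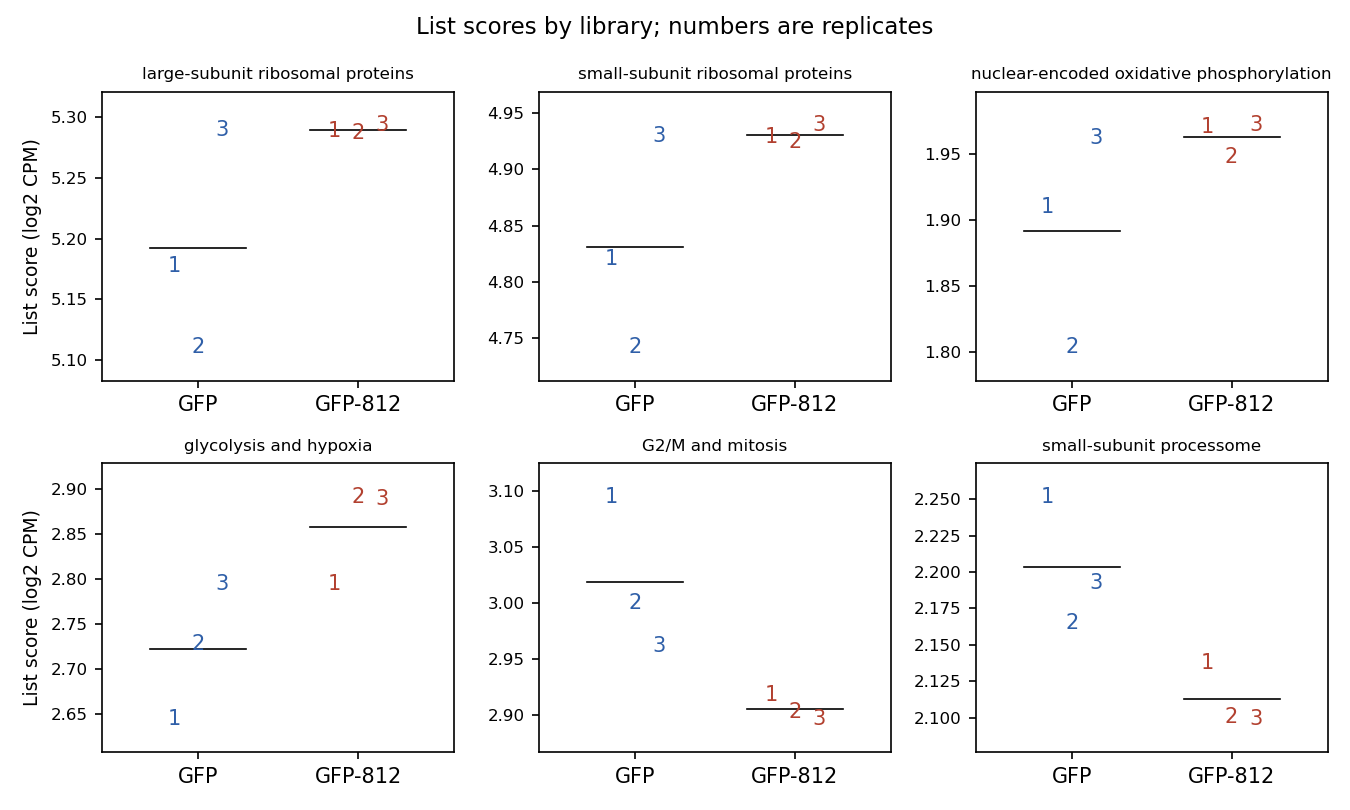
Scores of 6 gene lists in each library, as the mean log2 CPM of the members minus the library's median, with digits giving the replicate number, GFP in blue, GFP-812 in red and lines at the group means. GFP replicate 3 has ribosomal protein scores of 5.29 and 4.93, within the range of the GFP-812 libraries, while mitosis and processome scores of the groups do not overlap.

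Among cell division genes 7 of 36, and among DNA repair genes 5 of 49, were lower in GFP-812 cells. On the G2/M and mitosis list 7 of 36 members fell, 0 rose and 29 did not pass (14 fell and 1 rose adjusted over the list alone), with a median of -0.10. CENPE, a kinesin of the centromere, stood at 20.8 ± 0.524 against 25.7 ± 1.94 FPKM (SD, n = 3 each; log2 fold change -0.30, SE 0.0443), and DLGAP5, a spindle protein, at -0.18 (SE 0.0431). Of 49 DNA damage response and repair genes 5 fell, 0 rose and 44 did not pass (7 fell and 1 rose adjusted over the list alone), with a median of -0.03. The helicase BLM had a log2 fold change of -0.27 (SE 0.0483) and RAD52, a recombination protein, one of -0.36 (SE 0.0881). Camera passed mitosis (adjusted p = 5.12e-06) and DNA repair (adjusted p = 0.0249) downward, each at an adjusted p = 0.463 with an estimated correlation. The G1/S and DNA replication list did not pass (adjusted p = 0.107; 2 of 34 fell, 3 adjusted over the list alone). Fallen members numbered 0 without GFP-812 replicates 2 or 3 or GFP replicate 1, 1 without GFP-812 replicate 1 or GFP replicate 2 and 3 without GFP replicate 3, where 1 rose. On the list of nuclear body and paraspeckle genes 3 of 26 fell, 1 rose and 22 did not pass (10 fell and 2 rose adjusted over the list alone). CLK1, a kinase of splicing factors, fell to 15.8 ± 1.02 from 19.6 ± 0.898 FPKM (SD, n = 3 each), and NEAT1, the RNA that scaffolds paraspeckles, rose to 9.48 ± 0.641 from 7.4 ± 1 FPKM (SD, n = 3 each). Camera passed that list downward (adjusted p = 0.000358; adjusted p = 0.463 with an estimated correlation). Fallen mitosis genes numbered 1 without GFP-812 replicate 2 or GFP replicate 1, 3 without GFP-812 replicate 3 and 13 without GFP replicate 3. Fallen repair genes numbered 1 without GFP-812 replicates 1 or 2, 2 without GFP replicate 2 and 9 without GFP replicate 3, and fallen nuclear body genes numbered 5 without GFP replicate 2 and 10 without GFP replicate 3. DNA repair lost its camera call without GFP-812 replicate 1 (adjusted p = 0.13) or GFP replicate 2 (0.12, at a median of -0.01), and at a mean FPKM of at least 5 (0.15). On log2 CPM its adjusted p was 0.0292 before and 0.0687 after the GC and length correction, at edgeR medians of -0.0349 and -0.0356 (median absolute deviation 0.131 and 0.118). DLGAP5 lost its edgeR call without GFP-812 replicates 1 or 2 or GFP replicate 1 (0.0571 to 0.0751), and RAD52 lost its call without GFP-812 replicates 1 or 2 (0.0502 and 0.0737).

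Stress lists gave mixed results. Of 23 heat shock chaperones 3 fell, 0 rose and 20 did not pass (3 fell adjusted over the list alone), among them the co-chaperones CHORDC1 at a log2 fold change of -0.25 (SE 0.0414) and HSPH1 at -0.23 (SE 0.04). Of 20 aminoacyl-tRNA synthetases, which charge transfer RNAs, 3 fell, 0 rose and 17 did not pass (3 fell adjusted over the list alone), with TARS1 at -0.22 (SE 0.0394) and CARS1 at -0.18 (SE 0.0548). Among interferon response genes 2 of 24 rose, 0 fell and 22 did not pass (4 rose adjusted over the list alone), with IFIT1 at 0.35 (SE 0.0889) and IFI44L, at 0.3 ± 0.0794 against 0.16 ± 0.0458 FPKM (SD, n = 3 each), at 0.91 (SE 0.268). Camera passed chaperones (adjusted p = 0.0249; adjusted p = 0.545 with an estimated correlation) and synthetases (adjusted p = 0.0218; adjusted p = 0.49 with an estimated correlation) downward, and the interferon list upward (adjusted p = 0.00919; adjusted p = 0.463 with an estimated correlation). List medians were -0.0392 for chaperones (-0.0205 without GFP-812 replicate 3, -0.0693 without GFP replicate 2) and -0.0435 for synthetases (-0.0185 without GFP replicate 1). The interferon median was 0.0677 (0.00297 without GFP-812 replicate 2, 0.0375 without GFP replicate 1). It is over the 24 members tested by edgeR, of which 15 were higher and 9 lower. Camera used only 12 interferon members, and IFI44L lay under its filter. Chaperones lost their camera call without GFP-812 replicate 3 (adjusted p = 0.0929), GFP replicate 1 (0.0512) or GFP replicate 3 (0.248) and at a mean FPKM of at least 5 (0.107). Synthetases lost theirs without GFP-812 replicate 1 (0.0749) or GFP replicate 3 (0.123) and at a mean FPKM of at least 5 (0.0837). On log2 CPM their adjusted p was 0.038 before and 0.0541 after the GC and length correction, at edgeR medians of -0.0435 and -0.041 (median absolute deviation 0.072 and 0.0818). The interferon list lost its call with no filter (0.268) and on log2 CPM (0.0882 before and 0.0675 after the GC and length correction). Fallen synthetases numbered 1 in every fit without 1 library except that without GFP replicate 2, and risen interferon genes numbered 0 without GFP-812 replicate 2 or GFP replicate 2 and 1 without GFP-812 replicates 1 or 3 or GFP replicate 1. CARS1 lost its call in every such fit but that without GFP replicate 2 (adjusted p 0.0832 to 0.312), IFI44L without GFP-812 replicates 2 or 3 or GFP replicates 1 or 2 (0.114 to 0.273), and IFIT1 without GFP-812 replicates 1 or 2 or GFP replicate 2 (0.0684 to 0.114).

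The p53 target list did not pass camera (adjusted p = 0.374), with 1 of 27 members risen and 3 fallen (2 and 3 adjusted over the list alone). Risen and fallen p53 targets numbered 0 and 1 without GFP-812 replicate 3 or GFP replicate 1, 0 and 2 without GFP-812 replicate 2 and 2 and 4 without GFP replicate 3. PPM1D, a phosphatase that acts on p53, fell to 4.28 ± 0.403 from 5.79 ± 0.135 FPKM (SD, n = 3 each; log2 fold change -0.43, SE 0.068), and SESN2 had a log2 fold change of -0.26. The ATF4 integrated stress response did not pass as a list (adjusted p = 0.757), with 1 of 26 risen and 4 fallen (2 and 5 adjusted over the list alone). Its fallen members numbered 2 without GFP-812 replicate 3, and without GFP replicate 1 it had 0 risen and 3 fallen. PPP1R15A, which directs dephosphorylation of eIF2-alpha, fell (log2 fold change -0.42, SE 0.0679), and DDIT4, an inhibitor of mTORC1 signalling, rose (0.32, SE 0.0643). Immediate early genes did not pass (adjusted p = 0.888; 1 of 28 risen and 2 fallen by either adjustment), with ATF3 at -0.25 and IER5 at 0.23. Risen immediate early genes numbered 0 without GFP-812 replicates 1 or 2 or GFP replicates 1 or 2 and 2 without GFP replicate 3, and fallen ones 1 in every fit without 1 library except that without GFP replicate 3. SESN2 lost its call without GFP-812 replicate 3 (adjusted p = 0.178) or GFP replicate 1 (0.114), DDIT4 without GFP replicate 1 (0.0776, at a log2 fold change of 0.17), and IER5 without GFP-812 replicates 1 or 2 or GFP replicates 1 or 2 (0.0694 to 0.162).

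Lists for other cell types and RNA classes moved on few genes. Extracellular matrix and fibroblast markers passed camera upward (adjusted p = 0.00382; adjusted p = 0.463 with an estimated correlation), with 2 of 15 risen, 0 fallen and 13 not past (6 rose adjusted over the list alone). FN1, fibronectin, stood at 4.28 ± 0.186 against 2.91 ± 1.01 FPKM (SD, n = 3 each; log2 fold change 0.57, SE 0.0934), with 4.06 FPKM in GFP replicate 3 and a log2 fold change of 0.88 without it. ACTA2, smooth muscle actin, stood at 0.383 ± 0.0586 against 0.123 ± 0.0404 FPKM (SD, n = 3 each) and lost its call in every fit without 1 library except that without GFP replicate 3 (adjusted p 0.137 to 0.208). Risen markers numbered 1 without GFP-812 replicates 2 or 3 or GFP replicate 1, and 4 without GFP replicate 3. Camera used only 8 of these markers, and ACTA2 lay under its filter. Replication-dependent histones passed camera upward (adjusted p = 0.0335; adjusted p = 0.463 with an estimated correlation) although 0 of 7 members passed by either adjustment. H4C8 and H2BC5, with the smallest p, had log2 fold changes of -0.83 and 0.44 (adjusted p = 0.179 and 0.432). Camera used only 5 members. H4C8, at mean FPKM of 0.54 in GFP-812 and 0.977 in GFP libraries, lay under its filter. The list median was 0.162 (0.252, 0.0471 and 0.284 without GFP replicates 1, 2 and 3). The list lost its camera call without GFP-812 replicate 3 (0.0929) or GFP replicate 2 (0.239), with no filter (0.693), after quantile normalization (0.0646) and on log2 CPM (0.173 before and 0.26 after the GC and length correction). Blood cell, hepatocyte and keratinocyte markers had too few members at a mean FPKM of 1 for camera. Of their 1, 2 and 6 members tested by edgeR, 0 passed, and 1, 0 and 2 rose adjusted over the list alone.

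The other lists did not pass camera on all 6 libraries. Members risen and fallen over all genes tested were 0 and 0 of 48 for the primary cilium (adjusted p = 0.888), 0 and 0 of 10 for the never-in-mitosis kinases other than NEK1 (0.105), 0 and 2 of 32 for amyotrophic lateral sclerosis genes (0.466), 2 and 0 of 22 for motor neuron and axon genes (0.0697), and 0 and 0 of 22 for the endoplasmic reticulum unfolded protein response (0.888). They were 1 and 0 of 16 for NF-kB and inflammatory genes (adjusted p = 0.757), 1 and 0 of 23 for cholesterol synthesis (0.151), 0 and 0 of 31 for the proteasome (0.589), 1 and 0 of 33 for autophagy and lysosome genes (0.39) and 0 and 1 of 40 for translation factors (0.931). Counts adjusted over the list alone were the same except for motor neuron genes (3 risen) and translation factors (2 risen and 3 fallen). Without GFP replicate 3 cholesterol synthesis passed camera (adjusted p = 0.0308), with 4 members risen. Without GFP replicate 2 motor neuron and axon genes (0.038) and G1/S and DNA replication (0.0429) passed. Without GFP replicate 3 risen and fallen members also numbered 4 and 0 for NF-kB and inflammatory genes, 3 and 5 for translation factors, 4 and 3 for amyotrophic lateral sclerosis genes and 3 and 0 for the unfolded protein response. Fallen amyotrophic lateral sclerosis genes numbered 0 without GFP-812 replicates 2 or 3 or GFP replicate 1 and 1 without GFP replicate 2, and risen motor neuron genes numbered 1 without GFP-812 replicates 2 or 3 or GFP replicate 1. The single call of NF-kB genes was lost without GFP-812 replicate 2 or GFP replicate 2, and that of translation factors without GFP-812 replicates 2 or 3 or GFP replicate 1. The single call of cholesterol synthesis was lost without GFP-812 replicates 1, 2 or 3 or GFP replicate 1, and that of autophagy genes without GFP-812 replicates 1, 2 or 3 or GFP replicate 2. Median and mean differed in sign for the ATF4, mitochondrial and translation factor lists, and for immediate early genes both lay above 0 while camera pointed down.

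Of the 33 lists tested, 7 passed camera upward and 7 downward with the preset correlation, and 0 passed with an estimated correlation, where 1 had an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way on balance, passed 1. In both cases it was the list of nuclear body and paraspeckle genes. Its unadjusted camera p was 0.0226 with an estimated correlation, and its fry adjusted p was 0.0493. The mixed form of fry, which asks whether members change in either direction, passed 24 of the 33 lists. RNA polymerase I transcription was among them (mixed fry adjusted p = 0.00118). The large-subunit and small-subunit ribosomal protein lists were not (0.123 and 0.137).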

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

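limma-voom, limma on log2 CPM, robust edgeR, total-count scaling, the GC and length correction, the minimum mean FPKM of 1 or 20, camera with trended variance and camera on log2 CPM were chosen after the data were examined. On log2(FPKM + 1) limma called 3 genes in place of 647, 2 with a pseudocount of 0.1 or 0.5, 1 with 5, 3 with library totals made equal, 2 with quantile normalization, 4 without a trend, 6 with robust fitting and 3 with array weights. At least 2-fold, in place of 32, these were 3, 2, 2, 1, 3, 2, 2, 4 and 3. The prior degrees of freedom were 3.13 in that limma fit, against 51.5 in edgeR, 42.6 in limma-voom (669 genes) and 46 in limma on log2 CPM (614 genes), and limma called 101 genes, 1 of them at least 2-fold, at a mean FPKM of at least 20, where 2215 genes were tested. Why the prior was low on that scale was not tested. DESeq2 called 461 genes among 8019 with an adjusted p, 425 of them shared with the 647, and 1 at least 2-fold, for which the cause was not tested. edgeR called 8 genes at least 2-fold at a mean FPKM of at least 1 and 1 at a mean FPKM of at least 5, where fewer genes were tested. The count of changed genes stayed between 614 and 736 with no filter, both FPKM minimums, median-of-ratios or total-count scaling, robust fitting, protein-coding genes alone, limma-voom, limma on log2 CPM and the GC and length correction. Total-count scaling called 161 risen and 575 fallen (78.1% fallen) in place of 198 and 449 (69.4%). Without 1 library each it ranged from 209 (without GFP-812 replicate 2) to 1317 (without GFP replicate 3), and the count at least 2-fold from 13 (without GFP replicate 1) to 61 (without GFP replicate 3), for which the cause was not tested. The shared genes kept their direction in each of these settings. Similar counts did not mean the same genes. Of 640 calls at a mean FPKM of at least 5, where 7015 genes were tested, 484 were shared with the 647. After the GC and length correction 565 of 681 calls were shared.

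The NEK1 level in GFP-812 against GFP stayed past the threshold in each alternative run, at log2 fold changes of 5.89 (pseudocount 5) to 7.13. Of the 14 lists past camera, 11 could be tested at a mean FPKM of at least 5, and 7 of these passed and 4 did not. On log2 CPM 12 of the 14 passed before the GC and length correction and 10 after it. With the correlation estimated from 6 libraries 0 lists passed, and fry passed 1; the 2 ribosomal protein lists had estimated correlations of 0.875 and 0.856. Without 1 library each, 11 to 14 lists passed. No named gene and none of these 14 lists changed direction in the alternatives run for them. Medians of other lists did, such as RNA polymerase I transcription (-0.0407 on all libraries, 0.00552 without GFP-812 replicate 2). In counts simulated at this depth and replicate number, edgeR recovered 58.8% of changes of 0.3 on the log2 scale. That rate is for independent genes above a minimum mean count and not for all genes tested.

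Whether the replicate numbers pair the libraries stays open. Over all genes, deviations of same-numbered libraries from their group means correlated at -0.01 to 0.032, and not every library correlated best with its own number. The second principal component of log2 CPM (18.7% of variance), however, set both replicate 1 libraries apart. It was 20.6 in GFP-812 replicate 1 and 15.3 in GFP replicate 1, against -1.11 to -16.2 in the rest. With the replicate number as a block edgeR called 777 genes, 35 of them at least 2-fold, and camera passed 12 lists, with DNA repair and heat shock chaperones lost (adjusted p = 0.0526 each).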

Other observations

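The gene ontology terms in the deposited table, the space taken by NEK1 reads, the power of long genes and the gene sizes after the correction were examined only after the changed genes had been seen. Among 2059 terms of 10 to 500 genes, tested by Fisher's exact test against 12730 annotated genes and adjusted by Benjamini-Hochberg, risen genes were over-represented in cytoplasmic translation (19 genes, 2.46 expected, adjusted p = 9.45e-09), glycolytic process (8 genes, 0.537 expected, adjusted p = 3.2e-05) and cellular response to hypoxia (9 genes, 1.26 expected, adjusted p = 0.00229). The glycolytic genes were ALDOC, ENO1, ENO2, GAPDH, LDHA, PGK1, PGM1 and TPI1. Fallen genes were over-represented in double-strand break repair via homologous recombination (12 genes, 2.48 expected, adjusted p = 0.0119), among them BLM, RAD52, HELQ, XRCC2 and SMC5, in protein deubiquitination (11 genes, 2.58 expected, adjusted p = 0.0365), with USP1, USP8, USP15 and CYLD, and in regulation of cytokinesis (8 genes, 1.37 expected, adjusted p = 0.0365), with AURKA and PRC1. A logistic fit with expression and exonic size as covariates was run for the terms past the threshold. Its p-values, not adjusted over terms, were 7.75e-06, 2.41e-08 and 7.75e-08 for the risen terms in the order named. For the fallen terms they were 8.82e-06, 0.000888 and 0.000105. Other risen terms past the threshold in Fisher's test were translation, gluconeogenesis and positive regulation of gene expression. Another fallen term was cellular response to DNA damage stimulus (Fisher adjusted p = 0.0407, logistic p = 0.0127). GC content was not a covariate of the logistic fit. Genes are not independent replicates, and these tests treat them as such.

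The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 647 changed genes, 32 changed at least 2-fold and 14 lists past camera, and the highest of the others gave 0, 0 and 11. In each case 1 of the 10 splits, the real one, gave as many. The split that passed 11 lists set GFP-812 replicate 1 and GFP replicates 1 and 2 against the rest. All splits but the real one set most GFP libraries against most GFP-812 libraries, so part of a group difference stayed in each. With 0 genes called, they passed 0, 0, 5, 2, 7, 7, 11, 6 and 0 lists. That make-up alone thus does not account for the 11 lists. Whether a structure of the samples that crosses the groups added to the count was not tested.

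In GFP-812 libraries 16 of 47 large-subunit and 9 of 32 small-subunit ribosomal protein genes and 8 of 66 oxidative phosphorylation genes rose, and 7 of 36 mitosis and 4 of 51 processome genes fell. After the trends on GC content and exonic size were removed from each library, all 5 of these lists passed camera with the preset correlation in their direction and kept at least 0.5 of their median, which argues against those trends as the whole cause for these 5. Of the 14 lists past camera, 12 passed on log2 CPM before that correction, without interferon and histones, and 10 after it, when DNA repair (adjusted p = 0.0292 before and 0.0687 after) and synthetases (0.038 and 0.0541) lost their calls. The edgeR medians of DNA repair were -0.0349 and -0.0356 (median absolute deviation 0.131 and 0.118) and those of synthetases -0.0435 and -0.041 (0.072 and 0.0818), so these calls ended near the threshold with little change in the median. Before the correction the medians were nearest 0 at -0.0148 for DNA repair (without GFP replicate 2) and -0.0185 for synthetases (without GFP replicate 1). With an estimated correlation none of the 5 calls held before the correction (adjusted p 0.463 to 0.49). The space that NEK1 reads took up would shift every other gene by -0.0123 on the log2 scale (-0.0116 to -0.0132 over the 3 GFP-812 libraries), against absolute list medians of 0.0617 to 0.115. A shift shared by all genes cannot raise some lists and lower others, and TMM scaling is meant to remove it. The outcome was thus fixed before the comparison, which shows only how small the shift was. The scores of 2 of the 5 lists did not overlap between the groups. Of the 5, 0 had a gap wider than the larger of the ranges within the groups. The mitosis gap was 0.044, against ranges of 0.0207 within GFP-812 and 0.1329 within GFP. A shared axis of variation between libraries would give such scores, and GFP replicate 3 lay with the GFP-812 libraries in ribosomal protein scores. Such an axis and an effect of the GFP-812 plasmid both stay open, the latter untested apart from it.

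On the glycolysis and hypoxia list 12 of 33 genes rose, with a list median log2 fold change of 0.123 and a camera adjusted p of 0.463 with an estimated correlation. The median was 0.103 after the GC and length correction and the list still passed camera with the preset correlation (adjusted p = 1.35e-08), which argues against those trends as the whole cause. A candidate explanation is a broader hypoxia-like response in GFP-812 cells: the 150 genes that the table annotates to a response to hypoxia and that are not on the list passed camera upward (p = 0.0391; p = 0.0866 with an estimated correlation), with a median of 0.0409 over the 193 tested by edgeR. Of those 193, 9 rose, with HILPDA, PLOD2, FAM162A and STC1 among them, and 7 fell, with EGR1 among them. Cell density and oxygen in each culture are not given in the labels, so this stays a hypothesis. The list scores also varied within groups. In replicates 1, 2 and 3 they were 2.79, 2.89 and 2.89 in GFP-812 and 2.64, 2.73 and 2.79 in GFP. The groups overlapped, with ranges of 0.0973 within GFP-812 and 0.1501 within GFP. A shared axis of variation between libraries thus stays open for this list too.

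Fallen genes were longer than risen genes, with median exonic sizes of 7697 and 4171 bases, a difference of 3526 bases (permutation p = 1e-04, the smallest that 10000 permutations can give). The permutations, here and after the correction below, shuffled sizes among called genes, which are not independent replicates. Fallen genes also differed from risen genes in GC content. The median GC content was 41.8% in fallen genes and 47.9% in risen genes. Power for long genes acts on calls and not on fold changes, yet over all 16834 genes, called or not, the log2 fold change correlated with exonic size at -0.119 (Spearman; 0.104 with GC content), which argues against power as the whole cause. After the GC and length correction 92.9% of the fallen genes and 148 of the 198 risen genes still passed in the same direction. Among the 182 risen and 499 fallen genes called then, median sizes were 5729.5 and 6808 bases, a difference of 1078.5 bases (permutation p = 0.0101), and median GC content was 44% in both. The size difference among called genes narrowed and did not end. Over all genes tested, the Spearman correlation of log2 fold change after the correction was -0.00616 with exonic size and 0.00654 with GC content. The correction fits and removes these relations over all genes whatever their cause, so their absence after it tells nothing about the cause. The size difference left among called genes does not argue against a trend of the libraries. Such a trend stays open, for the GC content as well, and power for long genes stays open for the rest. An effect of GFP-812 on long transcripts was not tested separately and stays open as well, since the correction would remove it too.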
